A study of Mus musculus with 2 samples.

How the data were processed

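The table analysed holds log2 expression values of 20666 probe sets for 2 arrays of CFU-E cells, receptor-null per the protocol, 1 at 0 h and 1 at 3 h. Per the labels' protocols, biotinylated cRNA was made from 1.5 µg of total RNA with a one-cycle labelling assay. Per the submitters' processing notes, the deposited log2 values were made with RMA (background correction, quantile normalization and a summary over the probes of each probe set) and the affy package. Their versions and the arrays that were normalized together are not given in the sources used here. RMA gives all arrays the same distribution of probe values, so a shift of all transcripts between the samples could not be seen. The values ran from 2.02 to 14.73 at 0 h and from 1.93 to 14.73 at 3 h, with medians of 5.29 and 5.32. RMA also shrinks differences between dim signals, so folds near the floor may understate a change. An array has no read depth, and the number of arrays limits the precision.

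Samples were grouped by the time in their titles. The values were used as deposited, and no value was moved between scales. Probe sets were named from a platform annotation table: 17918 had 1 gene, 79 several and 2669 none. Those with several genes were named for none of them. Of the probe sets with 1 gene, 17767 were matched by Entrez ID to a table of RefSeq genes of the assembly GRCm38.p6, which changed 0 symbols, and the others kept the platform's symbol. No coordinates are given, since the sources tie the probe sets to no genome build. Probe sets of the same gene were averaged, which applied to 43 of 17874 genes, and in 19 of these the probe sets differed in sign. Of the unnamed probe sets 411 reached the floor, and 4 of these were at least 2-fold higher and 1 at least 2-fold lower at 3 h.

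A gene was counted where the higher of its 2 values reached a floor of 5.70, the median of all gene values. This left 9284 genes and set aside 8590, of which 69 differed by at least 2-fold. Differences are 3 h minus 0 h. With 1 array per group no test was made and no p-value computed, and a replicate check was not possible. Gene lists (18 main, 10 secondary, 8 of cell type markers and 2 of control genes), the threshold of 2-fold, the floor and the alternatives were fixed before the data were examined. For each list, the median difference of its members at or above the floor was placed among the medians of 10000 random lists of the same size, drawn from the same bins of mean expression (20 bins). The bound of at least 5 members for such a percentile was set after the data were examined. Lists share members, so their positions are not independent.

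The rule for the genes named was also fixed before the data were examined. It took the 12 genes with the highest and the 12 with the lowest difference at or above the floor whose probe sets agreed in sign. It also took Epor, Cish, Socs3, Pim1, Bcl2l1, Myc, Kit, Tfrc, Gata1, Klf1, Hbb-b1 and Alas2 whatever their values, and up to 4 members of each list with the largest absolute difference. Irf7, Irf9, Irf1, Bst2, Fos, Nfkb2, Osgin1, Mt1, Mt2, Rps16, Rps18, Hba-x, Apoh, Ahsg and Hnf4a were named after their values were seen. So were the most abundant cell type markers. A planned check of control probe sets for RNA quality was not analysed here, since the table used holds none.

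Alternatives were quantile normalization of both columns against each other, removal of an intensity trend (loess of the difference on the mean, span 0.3), the probe set with the highest mean in place of the average, probe sets without the suffixes that mark possible matches to several genes, no floor, and a floor at the 95th percentile of genes of other organs (6.52). For lists the mean in place of the median and 5 bins in place of 20 were also tried. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated data for the 3 h against 0 h comparison, with 9225 genes of which 200 were changed. The simulated noise was normal, with the same spread of 0.32 for all genes, taken from the differences between these 2 arrays. Changes were planted only in genes with a mean at least 2-fold above the floor. The 2-fold threshold then found 98% of genes changed by 1.5 and 88% of those changed by -1.5. It found 100% of those changed by 2 or -2 and passed 0.144% of unchanged genes. No replicate informed this noise, so 0.144% is not an estimate of false calls in these data. Of unchanged lists of 20 genes 5% lay outside the central 95%, and of lists shifted by 0.3, 92% lay above it.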

Results

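Gene expression was measured on 2 Affymetrix mouse arrays in colony-forming unit erythroid (CFU-E) cells, the progenitors that normally need erythropoietin to survive and divide, from embryos without the erythropoietin receptor. The cells came from fetal livers at gestational day 13.5. Red cells were lysed, and cells carrying myeloid, lymphoid, megakaryocytic or late erythroid surface markers, among them CD11b, GR1, CD14 and CD45, were removed with antibodies from pools of 40 to 50 livers. The purity of the sorted cells is not given in the sources used here, and the values describe all cells in each sample, whose hepatocyte and myeloid markers are given below. The cells were deprived of growth factors for 1 h and then either lysed at once (0 h, 1 array) or kept for 3 h in Panserin medium (3 h, 1 array). The comparison that the design allows is 3 h of culture against the start, within this genotype. There are no replicates, so no difference below has an error or a test, and the number of arrays limits the precision of every value. The treatment label of the 3 h sample names supplemental growth factors, whereas the treatment protocol says that none were added. The samples are therefore named by time. The genotype label names Epo and the protocol names its receptor. The protocol gives the strain BALB/c for the embryos, but only the 0 h sample has a strain label, and whether both samples came from one pool of livers is not stated in the sources used here. Differences are log2 values at 3 h minus those at 0 h.

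Epor, the deleted gene per the protocol, measured by 1 probe set, had log2 values of 7.08 at 0 h and 6.89 at 3 h. The genotype label names Epo, no wild-type array was analysed here, and the place of this probe set relative to the deleted part is not known. This level therefore checks nothing about the genotype. Y-linked Eif2s3y (7.67 and 7.99), Kdm5d (6.66 and 6.80) and Uty (6.33 and 6.32) and Xist, expressed in female cells (difference -0.55), were at or above the floor of 5.70 on both arrays. The median difference of these 4 sex-linked genes was 0.07. It cannot show a different share of female embryos, which would move Xist and the Y-linked genes in opposite directions. Xist was lower, Eif2s3y (0.33) and Kdm5d (0.14) were higher, and Uty differed by -0.01. Of 40 measured genes of other organs, 8 reached the floor on at least 1 array. Their median difference was 0.07, and the small heat shock protein gene Cryab differed most, at 1.49.

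Of 9284 genes at or above the floor, 186 (2.00%) were at least 2-fold higher at 3 h and 81 (0.873%) at least 2-fold lower, while 88.3% lay within 1.5-fold. At least 4-fold, 31 were higher and 3 lower. The gene that was higher by the most was Rtp4, an interferon-induced transporter protein gene, 20.8-fold (4.71 to 9.09). It was followed by Rsad2, which encodes the antiviral protein viperin (10.4-fold), the embryonic globin gene Hbb-bh1 (8.93-fold), Ifi202b (8.35-fold), Plet1 (8.30-fold), Sprr1a (7.73-fold), Cmpk2 (7.58-fold), Gbp2b (7.36-fold), Gbp2 (7.29-fold), the band 3 gene Slc4a1 (7.10-fold), Usp18 (7.03-fold) and Ifit1 (6.91-fold). Gbp2 and Gbp2b are close paralogs, so their probe sets may share signal. Among the genes named in this paragraph, Hbb-bh1, Ifi202b, Gbp2, Slc4a1 and Nfkbie were measured only by probe sets of the kind that can match several genes. The 3 genes at least 4-fold lower were the AP-1 gene Fosb (7.96-fold, 7.58 to 4.59), the NF-kB regulator gene Nfkbiz (4.18-fold) and the vasopressin receptor gene Avpr1a (4.03-fold). Next were Lin28a (3.90-fold), Tnfrsf13c (3.71-fold), Egr3 (3.57-fold), Nr4a1 (3.27-fold), Relb (3.24-fold), Hivep1 (3.22-fold), Fmo1 (3.16-fold), Prelid2 (3.12-fold) and Nfkbie (3.10-fold). Rtp4, Rsad2, Ifi202b, Sprr1a, Cmpk2, Gbp2b, Gbp2, Slc4a1 and Ifit1 were below the floor at 0 h. Fosb, Avpr1a, Lin28a and Tnfrsf13c were below it at 3 h. The folds of all these genes rest on a signal near background and are less certain. The robust SD of all differences at or above the floor was 0.32, and over all 20666 probe sets the arrays had a Pearson r of 0.990 and a Spearman rho of 0.988. Both are across probe sets, which are not independent replicates.

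**Figure D1:**
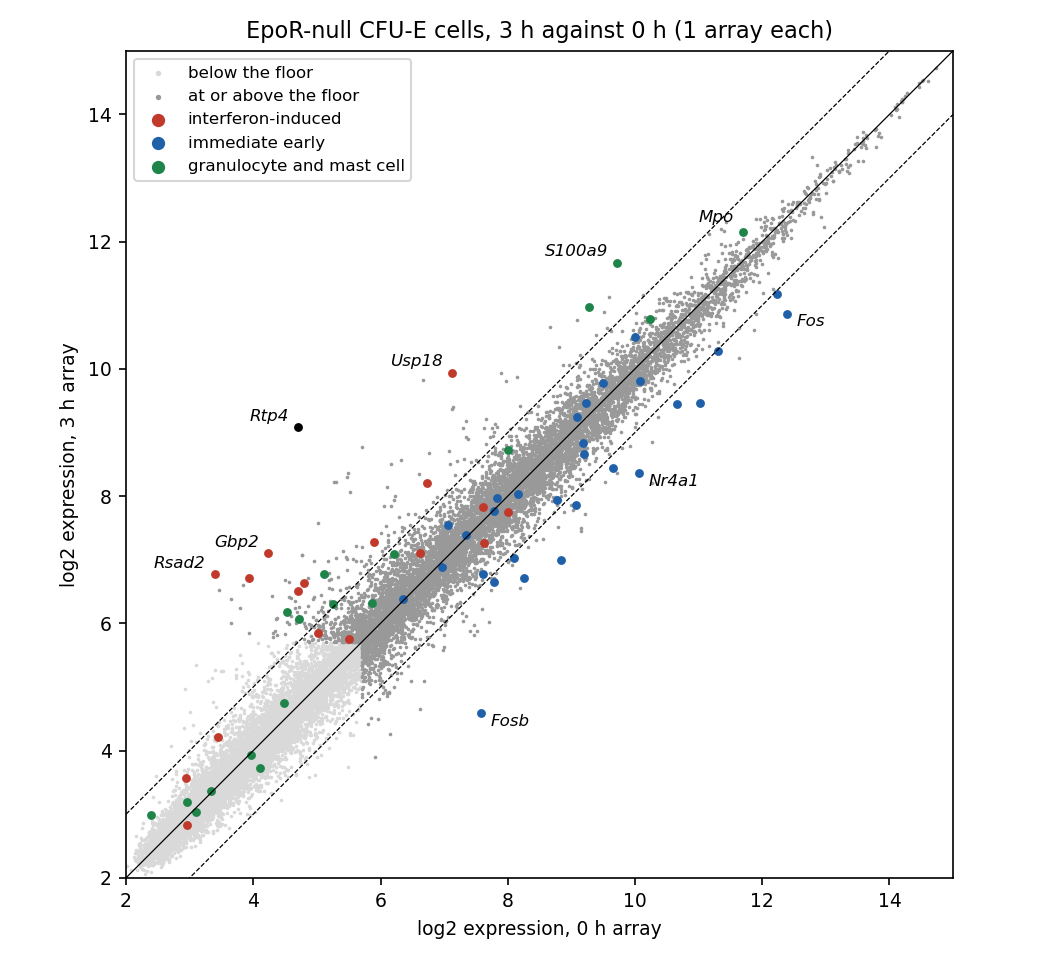
Log2 expression of each gene on the 0 h array (x axis) and the 3 h array (y axis), 1 point per gene, with dashed lines at 2-fold and gene lists in colour. Of 14 interferon-induced genes at or above the floor, 8 were at least 2-fold higher, among them Rsad2 (3.39 to 6.77). Of 29 immediate early genes, 13 were at least 2-fold lower, among them Fosb (7.58 to 4.59).

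Gene lists fixed before the data were examined were described by the median difference of their members at or above the floor. Each median was placed among those of 10000 random lists of the same size and matched mean expression. This describes these 2 arrays only. Of 34 lists with at least 5 such members, 16 lay outside the central 95% of their random lists, where 1.70 would be expected if genes varied independently. Members of a list may vary together, so more can lie outside without any effect of the 3 h. In the 3 h sample, granulocyte (median 1.06) and macrophage markers (0.56) were higher and hepatocyte markers (-0.18) lower, beside each list below.

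Interferon-induced genes were higher at 3 h as a group. Of 14 at or above the floor, 8 were at least 2-fold higher and none 2-fold lower, and the median of 1.44 lay above all 10000 random lists. Besides Rsad2, Gbp2, Usp18 and Ifit1 named above, the transcription factor gene Irf7 differed by 1.85 and Irf9 by 1.48. Only 7 of the 17 measured members reached the floor at 0 h, against 14 at 3 h, and with the members below the floor included the median was 0.83. Irf1 (-0.25) and Bst2 (-0.36) were lower. Markers of myeloid cells were higher in the same sample and are given below. Genes of NF-kB and inflammation went both ways: 3 of 14 were at least 2-fold higher and 4 at least 2-fold lower. The chemokine gene Ccl2 was 4.42-fold and the prostaglandin synthase gene Ptgs2 4.25-fold higher, whereas Nfkbiz, Relb, Nfkbie and Nfkb2 (-1.48), which encode NF-kB subunits or their regulators, were lower. Ccl2 (4.29) and Ptgs2 (4.57) were below the floor at 0 h. The median of this list was 0.12, within the random lists, and -0.24 with the floor at the level of genes of other organs, where its percentile was 1.78.

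Immediate early genes, which respond within minutes to growth factors or stress, were lower at 3 h. Of 29, 13 were at least 2-fold lower and none 2-fold higher, and the median of -0.83 lay below all 10000 random lists. Fosb, Egr3, Nr4a1 and Ier2 (-1.56) were lowest, and Fos went from 12.40 to 10.87. Heat shock genes were also lower, with a median of -0.34 over 14 genes, and 1 of 10000 random lists lay as low. The co-chaperone gene Dnajb1 was 2.40-fold lower and Hsph1 1.88-fold lower, while Hspb1 was 1.89-fold higher. Feedback genes of ERK signalling had a median of -0.12 over 12 genes, within the random lists, with Egr1 (-1.05) and the cyclin gene Ccnd1 (-0.81) lower and Fosl1 (0.98) higher.

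Among 18 genes induced by erythropoietin or STAT5 signalling, the median was -0.06 and lay within the random lists. At least 1.5-fold, 2 were higher and 5 lower. The feedback inhibitor genes Cish (-0.83) and Socs3 (-0.69) were lower, as were Spred2 (-1.23) and Trib3 (-1.12), and Pim1 differed by -0.24. The cell cycle inhibitor gene Cdkn1a (1.20) and the transferrin receptor gene Tfrc (0.61) were higher, and Myc (0.27) and Bcl2l1 (0.27), which encodes the survival factor Bcl-xL, differed by less than 1.5-fold.

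Genes induced by p53 were higher at 3 h: 8 of 18 were at least 1.5-fold higher and 1 lower, and the median of 0.52 lay above all random lists. Trp53inp1, which acts in p53-dependent stress responses, was 3.19-fold higher, Cdkn1a 2.29-fold and Perp 2.04-fold, whereas Btg2, also an immediate early gene, was 2.30-fold lower. Myeloid markers were higher in the same sample. Cell cycle inhibitor genes, which share Cdkn1a, Ccng1 and Btg2 with this list, had a median of 0.32 over 16 genes, and 6 random lists lay as high. The retinoblastoma gene Rb1 differed by 0.84 and Ccng1 by 0.69. The 13 pro-apoptotic genes had a median of 0.09, within the random lists, with the death receptor gene Fas (0.90), Apaf1 (0.73) and Bid (0.61) higher and Bnip3 (-0.71) lower. The 10 anti-apoptotic genes had a median of 0.19, also within them, and Naip2 (1.12) and Xiap (0.45) differed most. For 16 genes induced by FoxO factors the median was -0.13, at a percentile of 6.21. With no floor it was 0.13, and after quantile normalization -0.18, at a percentile of 2.49. The cyclin gene Ccng2 (0.60) was higher and Klf2 (-0.85) and Sod2 (-0.72) were lower.

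Genes of NRF2 and oxidative stress, with metallothioneins, had a median of 0.34 over 15 genes, above all random lists, with 10 higher and 5 lower. The quinone reductase gene Nqo1 was 2.92-fold and the sulfiredoxin gene Srxn1 2.54-fold higher, whereas Osgin1 (-0.40) and the metallothionein genes Mt1 (-0.30) and Mt2 (-0.32) were lower. Here too, myeloid markers were higher in the same sample. All 19 cholesterol synthesis and uptake genes at or above the floor were lower, 5 of them at least 1.5-fold, with a median of -0.39 below all random lists. Among them were Stard4 (-0.87) and Insig1 (-0.82), which encode a sterol carrier and a sterol sensor. Hepatocytes also express genes of lipid synthesis, and hepatocyte markers, given below, were lower in the same sample, among them Apob (-0.79) and Apoc1 (-0.75). The median was -0.22 for 14 fatty acid synthesis genes (percentile 1.04), where Scd1 differed by -0.61 and Gpam by -0.47. It was -0.26 for 32 genes of ribosome biogenesis and MYC-dependent growth and -0.30 for 31 genes of hypoxia and glycolysis, both below all random lists. In the first of these 28 were lower and 4 higher, with the spermidine synthase gene Srm (-0.997) and the nucleolar gene Nolc1 (-0.91) lowest, and Myc itself, at 0.27, was not among the lower genes. In the other 25 were lower and 6 higher, with Vegfa (-0.69) and Pfkl (-0.64) lower and Pfkfb4 (0.66) higher. The 27 cytosolic ribosomal protein genes had a median of -0.01, within the random lists, and none differed by 1.5-fold. Their median level at 0 h was 12.84, and array signals can saturate at high levels.

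Genes of the ATF4 stress response had a median of -0.09 over 31 genes, at a percentile of 9.99. Their mean, -0.18, lay at a percentile of 0.22 among means of random lists, with Atf3 (-1.20), Trib3 and Herpud1 (-0.85) lower and Chac1 (0.72) higher. The 16 genes of the unfolded protein response had a median of -0.07, and none differed by 1.5-fold. The 21 autophagy and lysosome genes had a median of 0.01, and in them the autophagy receptor gene Sqstm1 (0.76) was higher and the kinase gene Ulk1 (-0.76) lower. Glucocorticoid receptor targets had a median of -0.18 over 12 genes, at a percentile of 5.66, with Lcn2 (1.64), also one of the granulocyte markers, higher and Zfp36 (-0.83) lower. With no floor the median was -0.29, at a percentile of 0.12, and the mean of the 12 genes, Lcn2 included, was 0.0095. The 8 targets of TGF-beta and BMP had a median of -0.25, at a percentile of 2.42, which became 2.77 after removal of an intensity trend. Their mean, -0.13, lay at a percentile of 14.5 among means of random lists. Tgfb1 (-0.59) was lower and Smad6 (0.89) higher.

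In the cell cycle, 25 of 32 genes of G2/M and mitosis were higher and 7 lower. Their median was 0.18, and 4 random lists lay as high. Only 3 reached 1.5-fold: the kinetochore motor gene Cenpe (0.66), the kinase gene Plk1 (0.65) and Kif2c (0.64). The 33 G1/S and DNA replication genes had a median of 0.08, within the random lists, with Ccne2 (0.56) higher and Dtl (-0.72) and E2f2 (-0.69) lower, and their mean was 0.0035.

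Erythroid genes went both ways. Among 19 erythroid transcription factor and receptor genes, Nfe2 (1.11), Gata1 (0.83), Tal1 (0.78) and the glucocorticoid receptor gene Nr3c1 (0.70) were at least 1.5-fold higher and none was 1.5-fold lower. Klf1 (0.28) and Kit (0.02) differed less. The median was 0.05, within the random lists, and the mean 0.14. Among 21 haem synthesis and iron genes, 4 were at least 1.5-fold higher, namely Alad (0.82), Uros (0.80), the mitochondrial transporter gene Abcb10 (0.66) and Tfrc. The median was 0.14, at a percentile of 97.6, which became 97.3 after removal of an intensity trend. Alas2, the erythroid enzyme of the first step of haem synthesis, was below the floor on both arrays (4.49 and 4.72). A value below the floor from a single probe set does not show that a gene is off. The ribosomal protein genes Rps16 (2.86 and 2.97) and Rps18 (3.09 and 2.82) were below the floor as well. Red cell membrane and late erythroid genes had a median of 0.12 over 20 genes, within the random lists: Slc4a1 (2.83) and Sptb (0.68) were at least 1.5-fold higher, and Aqp1 (-1.13) and Icam4 (-0.81) were among 4 lower by that much. The 3 globin genes at or above the floor, Hbb-bh1 (6.67 to 9.83), Hbb-b2 (4.57 to 5.99) and Hbb-y (8.16 to 8.85), were all higher, with a median of 1.43. Their probe sets, like that of Slc4a1, are of the kind that can match several genes, and globin paralogs may share signal. With no floor the median over 6 globin genes was 0.66. Hbb-b1, in the list of genes to be named, was not analysed here.

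**Figure D2:**
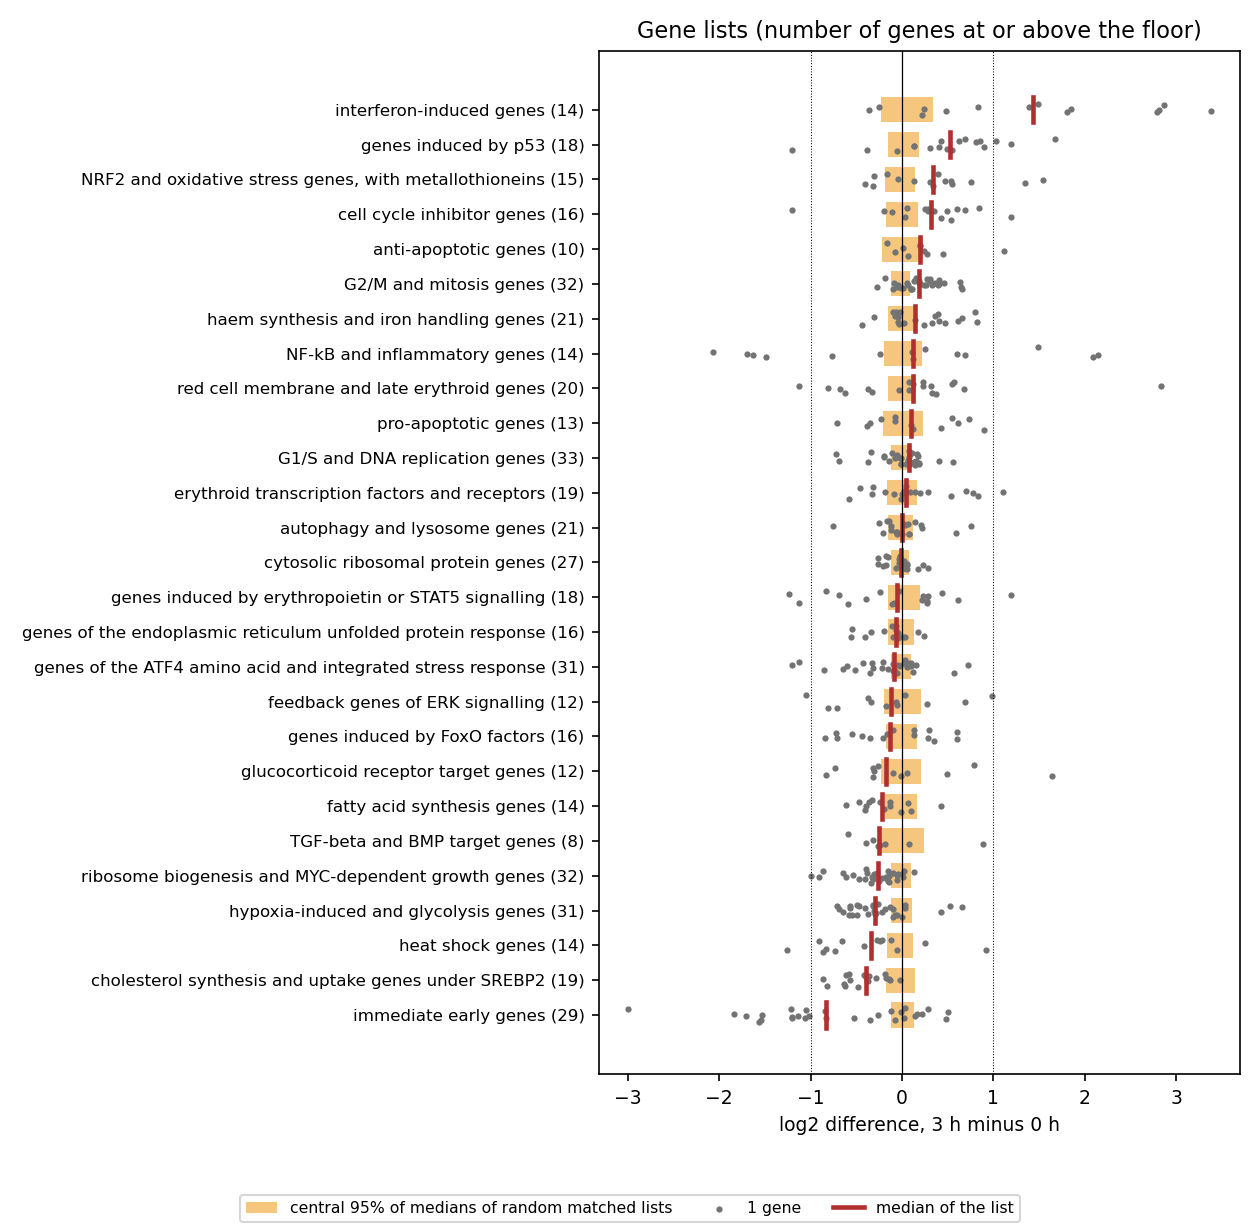
Log2 difference, 3 h minus 0 h, of the members at or above the floor (points) of each gene list, other than cell type and control lists, with at least 5 such members, the median of the list (red line) and the central 95% of medians of 10000 random lists (orange band). Among the lists drawn, which leave out the 3 globin genes, the interferon-induced list has the highest median (1.44) and the immediate early list the lowest (-0.83).

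Markers of other cell types were measured in both samples. All 20 measured hepatocyte markers were at or above the floor on both arrays, and the most abundant of them, named after their values were seen, were Afp (14.60 and 14.53) and Alb (14.15 and 13.96). Hepatocyte markers were lower at 3 h in 18 of 20 (17 after quantile normalization), with a median of -0.18 (25 random lists as low), and Apob (-0.79) and Apoc1 (-0.75) were lowest, whereas the keratin genes Krt8 (0.95) and Krt18 (0.88) differed most and were higher. By a split chosen after the values were seen, the 4 markers below 10 at 0 h (Apob, Apoh, Ahsg and Hnf4a) had a median of -0.64 and the 16 others one of -0.12. Array signals can saturate at high levels, so the median of all 20 may understate the difference, but the split does not show that. Among the 16 others, Apoc1 (10.37 at 0 h) was lower, and Krt8 (11.17) and Krt18 (11.44) were higher. Granulocyte and mast cell markers were higher in all 11 members at or above the floor, with 6 at least 2-fold higher and a median of 1.06, above all random lists. The calprotectin genes S100a9 and S100a8 were 3.85-fold and 3.24-fold higher, Camp 3.19-fold and Lcn2 3.13-fold, and the most abundant marker, Mpo, named after its values were seen, went from 11.70 to 12.15. At 0 h 7 of these 18 measured markers reached the floor, and with no floor the median was 0.57. Macrophage and monocyte markers had a median of 0.56 over 10 genes, above all random lists, and 0.17 with no floor. The lysozyme gene Lyz2, a paralog of Lyz1, was 3.55-fold higher, Csf1r 2.00-fold and Fcgr3 1.74-fold, and Vcam1 was 1.97-fold lower. These myeloid markers were present although antibodies against CD11b, GR1, CD14 and CD45 had been used to remove such cells. Of 4 megakaryocyte markers at or above the floor, Gp1bb was higher by 2.19 and Gp9 by 0.47, Pf4 (0.07) and Itga2b (-0.09) differed little, and the median was 0.27. At 0 h Gp1bb was below the floor (4.49). Of 14 lymphoid markers only Ighm (0.74) reached the floor. Medians lay within the random lists for 10 stromal markers (0.11, with Acta2 at 1.08), 6 endothelial markers (-0.05, with Esam at 0.49) and 10 early progenitor markers (0.19, with Gata2 at 0.62 and Hlf at -0.95).

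**Figure D3:**
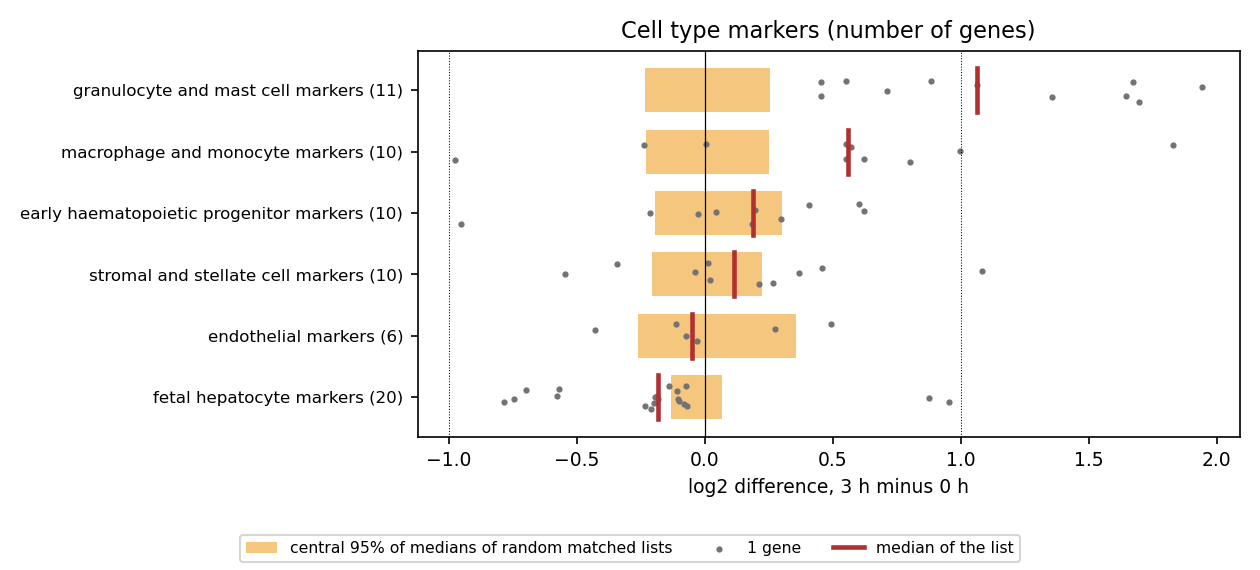
Log2 difference, 3 h minus 0 h, of cell type markers at or above the floor (points), with the median of each list (red line) and the central 95% of medians of 10000 random lists (orange band). Granulocyte and mast cell markers (1.06) and macrophage markers (0.56) lie above the band, and hepatocyte markers (-0.18) below it.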

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

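With 1 array per group no alternative could leave out a replicate, and no paired analysis was possible because each group holds a single array. The count of genes at least 2-fold higher ranged from 132 (higher floor) to 237 (no floor) around 186, and that of lower genes from 62 to 99 around 81 under the same settings, within 1.5 times in 12 of 12 cases. All 919 values of genes named by the fixed rule differed under alternatives from the reported ones by at most 0.073. These genes have 1 probe set each, so only quantile normalization and removal of the trend could change their values. Genes without a value under a setting were left out of it, so this count says little about robustness. Of 303 list values, 280 moved by less than the SD of their random lists (for the 4 lists with under 5 members, by less than 0.32, the robust SD over genes), 23 by more, and 0 of the lists outside the central 95% turned direction. Of those 16 lists, 14 stayed outside after quantile normalization and 14 after removal of an intensity trend, and between 15 and 16 under each other setting. With no floor, which adds members near background, the medians were 0.83 for interferon-induced, 0.57 for granulocyte and mast cell, 0.17 for macrophage, 0.66 for globin, 0.13 for FoxO and 0.044 for lymphoid genes. With the floor at 6.52, which removes dim members, they were 0.88 for granulocyte and mast cell, 1.93 for globin, 1.05 for megakaryocyte, -0.018 for FoxO, -0.31 for glucocorticoid and -0.24 for NF-kB genes. Means in place of medians were -0.70 for immediate early, -0.18 for ATF4, 0.0035 for G1/S, 1.76 for globin, 0.14 for erythroid factor, -0.028 for NF-kB, 0.0095 for glucocorticoid and 0.66 for megakaryocyte genes. Removal of the trend gave -0.13 for hepatocyte and 0.048 for ribosomal protein genes. Leaving out probe sets that may match several genes removed all 3 globin genes counted and left 0.61, the value of Hba-x alone, admitted by the lower floor of that setting. Beyond what these settings change by construction, the cause was not tested. Signal near background limits the lists with few members above the floor.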

Other observations

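Removal of an intensity trend was planned before the data were examined. Its use as a test, the other tests in this part, the grouping of genes by symbol and the genes named here were chosen after the results were seen. Among 145 families of at least 8 genes at or above the floor that share a symbol stem, 14 lay below and 11 above the central 95% of matched random lists. If genes varied independently, 7.25 in all would be expected, but genes of a family may vary together. Mitochondrial ribosomal protein genes were lower at 3 h by small amounts: 26 of 27 Mrps genes (median -0.22) and 37 of 45 Mrpl genes (median -0.17), against a median of -0.01 for the cytosolic ribosomal protein genes. The latter had a median level of 12.84 at 0 h, where array signals can saturate, so this contrast is weak. Genes of the RNA exosome (Exosc, 9 genes, median -0.39), of mitochondrial inner membrane import (Timm, 13 genes, -0.28) and of N-glycan assembly (Alg, 12 genes, -0.32) were lower too. Kinesin genes (Kif) were higher in 19 of 22, with a median of 0.34, and some of them are also in the G2/M list. Trim genes had a median of 0.30 over 26 genes, with Trim30a, an interferon-induced gene, highest at 2.77. ESCRT-III genes (Chmp) had a median of 0.36 over 9 genes. The medians of these families kept their sign after quantile normalization and after removal of an intensity trend.

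Cyp1a1, the classical target of the aryl hydrocarbon receptor, was higher at 3 h by 2.26 (7.14 to 9.40). Its relative Cyp1b1 was higher by 1.15, and Tiparp, another target of that receptor, differed by 0.05. Of 8 Cyp genes 6 were lower. The urokinase receptor gene Plaur (2.24), Lgals3 (2.34), S100a6 (2.55) and Anxa1 (1.55) were higher too. Myeloid cells also express these 4 genes, and granulocyte (median 1.06) and macrophage markers (median 0.56) were higher in the same sample. No explanation was tested for these values.

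Interferon-induced genes were higher at 3 h by a median of 1.44, and 1.41 after removal of an intensity trend, which argues against that trend. The random lists are matched on mean expression, so the position among them adds nothing on this point. The median exceeded that of 21 myeloid markers (0.71, SD 0.72 over markers) by 0.72, but lay below the highest of them, S100a9 (1.94). The 4 highest genes, Rsad2 (3.38), Gbp2 (2.87), Usp18 (2.81) and Ifit1 (2.79), lay above it, which more myeloid cells of the same state would not give if S100a9 marked their share. Of these genes, only Usp18 was above the floor at 0 h. For the list as a whole, more myeloid cells cannot be told apart from induction, since the markers range from -0.98 to 1.94 and give no single share. An interferon response in any of the cells, activation of remaining myeloid cells, the time in culture or a difference between pools may also account for it, and each time has 1 array.

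Immediate early genes were lower at 3 h by a median of -0.83, and -0.84 after removal of an intensity trend, which argues against that trend. A general loss of short-lived transcripts would lower others as much, but 8 short-lived transcripts (Myc, Mcl1, Mdm2, Pim1, Id1, Hes1, Socs3 and Odc1) had a median of -0.16 with an SD of 0.42 over genes. They ranged from -0.69 to 0.63, and some answer to signals of their own. Mdm2, for example, is also in the p53 list, which was higher. No half-lives were measured, so these 8 genes cannot exclude such a loss. A candidate explanation, not tested, is that dissociation and sorting had raised immediate early genes before 0 h. An effect of the presence or absence of growth factors during the 3 h was not tested, since the labels of the 3 h sample disagree on them and each time has 1 array.

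Granulocyte and mast cell markers were higher at 3 h by a median of 1.06. A smaller hepatocyte share alone would raise markers of all other cells, but 16 stromal and endothelial markers had a median of 0.015 with an SD of 0.40. If the same cells had only been more numerous, their genes would differ alike, unless high signals saturated or dim differences were shrunk. Neither was checked for these genes. Taken whatever the floor, 6 late granule or neutrophil genes exceeded the early granule genes Mpo, Elane, Prtn3 and Ctsg (from 0.45 to 0.88) by 1.03 in the medians, but while S100a8, S100a9, Camp, Ngp and Lcn2 lay above every early gene, Ltf (0.26), below the floor on both arrays, lay under them all, so a larger number of the same cells cannot be told apart from a shift to more mature ones. A change of their expression, expression of S100a8, S100a9 and Lcn2 in other cells, or a difference in how well the antibodies against GR1 and CD11b removed such cells may also account for it and was not tested.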
